A study of Mus musculus with 12 samples.

How the data were processed

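RNA sequencing was carried out on 12 libraries of mouse CD8 T cells, 2 in each of 6 groups. The cells carried a Tcf7-YFP reporter, in which yellow fluorescent protein reads out the activity of Tcf7, the gene of the transcription factor TCF1. The naive group was sorted from spleen as CD44 negative and reporter positive. The antigen-experienced group was sorted from spleen as CD44 positive and reporter positive. CD44 is encoded by Cd44. Another marker of these sorts and some genes that the rule below takes are not reported here. The day 3 effector group was CD8 T cells activated ex vivo for 3 days. For the other 3 groups, activated cells were sorted by reporter level on day 3, cultured further and sorted again by reporter level on day 9. These groups are called high-from-high, high-from-low and low-from-low, the word after "from" giving the day 3 sort. Groups and replicate numbers were taken from the sample labels. Nothing in the labels says that replicates came from separate animals or cultures, so p-values measure only the spread between these samples, which may be technical. The labels do not say that a replicate number marks a shared animal, culture or batch, and the numbers were not taken to pair samples.

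Per the submitters' processing notes, reads were processed with kallisto 0.46.1, DESeq2 1.30.1 was used, and the genome builds named are GRCm38 and mm10. kallisto assigns reads to transcripts by pseudoalignment. Each deposited table used here lists, per the file headers, an estimated count, an effective length and a TPM, an abundance scaled by transcript length and library size, for 118489 transcripts. The strand setting, the transcript index and any read trimming are not given in the sources used here. A second deposited file of each library repeats the estimated counts and was not used here. The effective length is in bases, per the file headers, and entered only an alternative fit.

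Transcripts were matched to genes by identifier with the GENCODE M21 annotation of GRCm38, from which gene symbols and coordinates were taken. Of the transcripts, 116816 matched 36047 genes. The 1673 that did not match held between 0.631% and 0.72% of a library's estimated counts and were left out. Estimated counts were summed per gene and rounded to whole numbers. Totals were 17147395 to 28285110 estimated counts per library. At this depth the median standard error of a log2 fold change, over the 10074 genes with a mean of at least 5 CPM (counts scaled to a common library size), was 0.15 in 5 comparisons and 0.16 between day 3 effector and naive cells. kallisto splits reads that fit several transcripts, so values of genes related in sequence (the Klra and Gzm families, Klrc1 and Klrc2, the Ifi20 family, Ccl3 and Ccl4, Hspa1a and Hspa1b) and of overlapping genes (Foxp3 and Ccdc22) are uncertain. Xist was not analysed here.

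Genes were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, after TMM normalization and edgeR's default low-count filter, which kept 15458 genes. All 12 libraries entered 1 fit, so the 6 groups shared the estimate of the spread. Dispersion and quasi-likelihood fits were robust, and fold changes used edgeR's default prior count. A prior count of 2 was used only for log2 CPM values (principal components, list means and replicate differences). Tests were two-sided, and p-values were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. The standard error of a log2 fold change was its size divided by the square root of the F statistic. CPM values in the text are normalized by TMM, are given per library or as mean ± SD, and rest on 2 libraries per group. Where a gene had no count in both libraries of a group, the fold is a lower bound against a floor of 3 counts per library. Where it had 1 to 3 counts, the ratio is given with its 95% exact interval. Floors and intervals cover counting error only. The fit was tested on simulated data with 200 genes changed by 2-fold or 4-fold. In the design of high-from-high against low-from-low, 73 of 100 genes changed 2-fold and 98 of 100 changed 4-fold were called, with 13 false calls among 184. In the design of antigen-experienced against naive these were 87 and 96 of 100, with 10 false calls among 193. The changed genes were at 5 CPM or more. With 200 genes changed the adjustment is less strict than with few, so these shares do not carry over to the day 9 comparisons. In the observed high-from-high against low-from-low comparison, Foxp3 (4.54-fold lower) and Klrc1 (4.41-fold lower) missed the threshold.

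Before the data were examined, 26 gene lists, the comparisons, the tests, the alternative settings and the rule for named genes were fixed. The lists covered naive and memory T cell genes, effector and cytotoxic genes, inhibitory receptors and exhaustion, virtual and central memory, cell cycle, glycolysis, hypoxia response, mitochondrial respiration, fatty acid oxidation, cholesterol synthesis, amino acid and stress response, interferon response, chemokine receptors and adhesion, cytokines and their receptors, immediate early and AP-1 genes, chromatin and DNA methylation, T helper and other lineage transcription factors, Wnt and TCF1-associated genes, and heat shock and dissociation. Marker lists covered B cells, myeloid and dendritic cells, neutrophils, erythroid cells and platelets, NK and gamma-delta T cells, CD4 T and regulatory T cells, and stromal and epithelial cells. Lists were tested with camera from limma 3.58.1 at its preset correlation of 0.01, which asks whether a list's genes moved more one way than the other genes. The sort genes, among them Tcf7, Cd44, Cd8a and Cd8b1, were left out of list tests, and 24 lists had at least the 3 tested members needed. Benjamini-Hochberg adjustment ran over the 144 tests of 24 lists in 6 comparisons. Of these, 57 passed the threshold, and 2 did with an inter-gene correlation estimated from the data. fry, which tests whether a list's genes moved one way on balance, called 46. Camera called 0 and 1 of 100 random sets of 30 unchanged genes in data simulated for the 2 designs above, and fry called 3 and 8. The simulated genes were drawn independently, so these sets cannot show how camera treats lists of correlated genes. In high-from-high against low-from-low cells, estimated correlations ran from −0.035 (myeloid markers) to 0.796 (cell cycle genes). Counts of a list's members that rose or fell are given from the adjustment over all genes and, where they differ, adjusted over the list alone.

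The genes named for a comparison were those 10 with the largest rise and 10 with the largest fall among genes past the threshold, at 5 CPM or more in the higher group and without overlap between the libraries of both groups. Predicted genes, genes without a symbol, pseudogenes and immunoglobulin or T cell receptor segments were excepted. Up to 4 genes of each list past the threshold, with the smallest p, were added. Tcf7, Cd44, Il7r, Ccr7, Lef1, Gzmb, Ifng, Prf1, Klrg1, Tox, Pdcd1 and Mki67 were followed in every comparison. Some members of the rule's larger sets are left out for length, lowest ranks first.

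The alternative settings fixed with them were DESeq2's size factors, the DESeq2 1.42.0 Wald test, no low-count filter, a strict filter (5 CPM in at least 2 libraries), a fit of only the 4 libraries compared, the replicate number as a block, transcript length offsets, limma on log2 (TPM + 1) and log2 (TPM + 0.1), and a fit without each replicate in turn. In the last, the lone library of a group is assumed to vary like the other groups. Another 7 settings for the day 9 comparisons were chosen after seeing the data. Comparisons against shared libraries were set beside 20 simulated draws of unchanged groups.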

Results

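RNA was measured in 12 libraries of mouse CD8 T cells, 2 in each of 6 groups. Naive and antigen-experienced cells came from spleen, where the latter carry CD44, a surface marker kept after an encounter with antigen. Day 3 effector cells had been activated ex vivo. The other 3 groups were day 9 cultures sorted by a reporter of Tcf7, the gene of TCF1, a transcription factor of naive and memory T cells, on day 3 and again on day 9. Library totals ran from 17147395 to 28285110 estimated counts. Between 17488 and 18668 genes had at least 1 count in 11 libraries, and 15050 had one in naive replicate 1.

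The sort genes were read first, as a check of the labels. Tcf7 (chromosome 11, 52252371 to 52283014, GRCm38) stood at 1180 to 1210 CPM in the naive libraries, 1160 and 1170 CPM in the antigen-experienced ones and 27.3 and 30.4 CPM in the day 3 effector ones. On day 9 it was at 513 and 535 CPM in high-from-high, 397 and 475 CPM in high-from-low and 159 and 284 CPM in low-from-low cells. Cd44 was at 1.38 and 1.45 CPM in naive cells and at 165 and 176 CPM in antigen-experienced cells. Cd8a was at 260 CPM or more in all 12 libraries. Klrg1, a marker of terminal effector cells, was at most 0.16 CPM and was not tested. In a principal component analysis of all 12 libraries, PC1 (48.6% of the variance) placed the day 3 effector libraries at 157 and 162 and the naive ones at −107 and −87.2. The 6 day 9 libraries lay between −8.46 and 13.1 on PC1 and between 55.5 and 68.7 on PC2 (29% of the variance), apart from all the other libraries, which were between −87.1 and −42.0 on PC2.

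**Figure D1:**
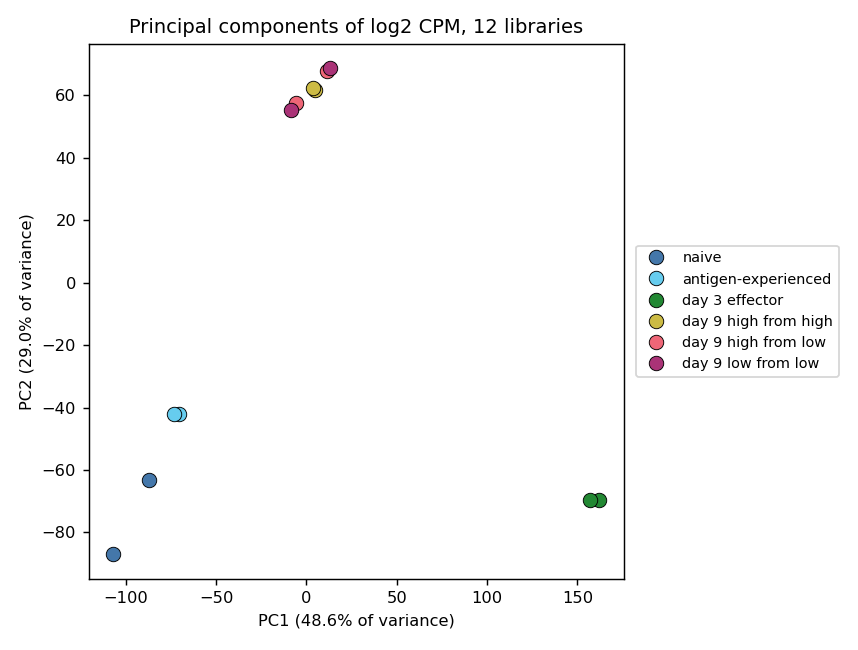
Principal components of the 12 libraries from log2 CPM, with PC1 (48.6% of the variance) on the horizontal and PC2 (29%) on the vertical axis, 1 point per library and 1 colour per group. The 6 day 9 libraries lie together at 55.5 to 68.7 on PC2, and the day 3 effector libraries at 157 and 162 on PC1.

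High-from-high and low-from-low cells were compared to find how day 9 cells with a high reporter at both sorts differed from cells with a low reporter at both. Klrk1, which encodes the activating receptor NKG2D (chromosome 6, 129610323 to 129623864), was at 29.1 ± 6.93 CPM (SD, n = 2) against 72.0 ± 2.89 CPM (SD, n = 2), a log2 fold change of −1.30 ± 0.15 (SE). It was the only gene of the 15458 tested that passed edgeR's threshold (adjusted p = 0.0462). Among 20 simulated draws of unchanged day 9 groups, draw 1 held 1 lower call here, and draw 8 held 1 higher and 1 lower. A single call can thus arise without a difference between the groups. Of the 38 effector and cytotoxic genes tested, 29 had a negative estimate, 1 fell over all genes tested, and 9 fell adjusted over the list alone. Those 9, chosen for naming after their values were seen, were Klrk1, Prf1, Klrc1, Klrc2, Il2ra, Ifng, Gzma, Klrd1 and Prdm1.

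Prf1, which encodes perforin, the pore-forming protein of cytotoxic granules, was at 11 ± 2.44 CPM against 23.9 ± 2.19 CPM (log2 fold change −1.13 ± 0.16, adjusted p = 0.0794 over all genes). Klrc1 and Klrc2, genes of NKG2 receptor chains, had log2 fold changes of −2.14 ± 0.34 and −2.30 ± 0.35 (adjusted p = 0.12 and 0.0794), and their reads can be split between them. Il2ra, the gene of the alpha chain of the interleukin 2 receptor, was at 609 and 610 CPM against 829 and 873 CPM (−0.48 ± 0.10). Gzma, the gene of granzyme A, was at 8.29 and 17.6 CPM against 52.1 and 319 CPM, and Klrd1, the partner chain of NKG2 receptors, at 61.3 and 83.3 CPM against 97.5 and 119 CPM. Prdm1, the gene of the repressor Blimp-1, had a log2 fold change of −0.92 ± 0.28 and Ifng, the gene of interferon gamma, one of −0.85 ± 0.26. Gzmb, the gene of granzyme B, was at 757 ± 54.2 CPM against 1610 ± 912 CPM (−1.09 ± 0.56, adjusted p = 1). The libraries did not overlap (719 and 795 against 966 and 2260 CPM), but the low-from-low ones differed widely.

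In camera's test the effector and cytotoxic list fell relative to other genes (adjusted p = 4.12e-27). The test's outcome was adjusted p = 0.0539 with an estimated correlation, and it ranged from 1.12e-33 to 0.0539 over 11 alternatives. Among the 23 virtual and central memory genes, 18 were lower, 1 fell over all genes and 3 fell adjusted over the list alone: Klrk1, Klrd1 and Ly6c2, which encodes a Ly6C surface protein of memory and effector CD8 cells. Ly6c2 was at 737 and 763 CPM against 1080 and 1360 CPM. This list fell too (camera adjusted p = 3.71e-06, and adjusted p = 0.0966 with an estimated correlation). Among 7 CD4 and regulatory T cell markers, 6 were lower and Foxp3 fell adjusted over the list alone. The list's camera adjusted p was 1.83e-05, with adjusted p = 0.0966 with an estimated correlation. Foxp3, the transcription factor gene of regulatory T cells (chromosome X, 7573644 to 7595245), was at 34.1 and 32.0 CPM against 186 and 114 CPM, a log2 fold change of −2.18 ± 0.27 (adjusted p = 0.0642 over all genes). Cd4 itself was at most 0.27 CPM in the low-from-low libraries. These 3 list results kept their direction and call whichever of the 4 libraries was left out, but fry called neither the virtual and central memory list (adjusted p = 0.0839) nor the CD4 and regulatory T cell list (adjusted p = 0.0946).

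Of 34 naive and memory T cell genes without the sort genes, Dapl1 and Myb rose and Ly6c2 fell adjusted over the list alone, and none passed over all genes. Dapl1, a gene of naive T cells, was at 1.88 and 1.39 CPM against 0.252 and 0.22 CPM. Myb, a transcription factor gene linked to T cell self-renewal, was at 53.9 and 56.1 CPM against 37.3 and 28.8 CPM. The list did not pass (camera adjusted p = 0.0759, and adjusted p = 0.733 with an estimated correlation). It passed upward with the strict filter (0.0377) and without low-from-low replicate 1 (4.44e-09) or high-from-high replicate 2 (0.00726), and without low-from-low replicate 2 it leaned downward (0.157). Cell cycle genes were higher in 31 of 38 cases (camera adjusted p = 0.00051, and adjusted p = 0.752 with an estimated correlation), but the direction turned without low-from-low replicate 1 (3.74e-06). Lower on balance were cholesterol synthesis genes (0.00368, and adjusted p = 0.568 with an estimated correlation), interferon response genes (0.000306, and adjusted p = 0.642 with an estimated correlation) and immediate early and AP-1 genes (0.0298, and adjusted p = 0.575 with an estimated correlation). No single member of these 4 lists passed, and fry called none of them, with adjusted p of 0.812 for cell cycle, 0.542 for cholesterol synthesis, 0.653 for interferon response and 0.656 for immediate early genes. The cholesterol call was lost without high-from-high replicate 2 (0.39) or low-from-low replicate 2 (0.841). The interferon direction turned without low-from-low replicate 2 (0.78), and the immediate early call was lost with length offsets (0.129) or without low-from-low replicate 1 (0.379) and turned without high-from-high replicate 2 (0.288). The inhibitory receptor list, the metabolic lists other than cholesterol, and the chromatin, T helper, Wnt, heat shock, chemokine and cytokine lists did not pass, with camera adjusted p from 0.0707 for cytokines to 0.986 for heat shock. In the T helper and cytokine lists, 1 gene each fell adjusted over the list alone. For amino acid, heat shock, Wnt and NK genes the median, mean and test direction did not all share a sign.

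In edgeR 347 genes had an unadjusted p under 0.05. In the data simulated for this design, 725 unchanged genes had such a p. edgeR thus gave fewer small p-values here than in that simulation, whose genes were drawn independently. The cause was not tested, and edgeR's few calls do not show that the groups are alike. The DESeq2 Wald test called 25 genes, 8 higher and 17 lower in high-from-high cells, against 1 in edgeR. Several are named here after their values were seen. Besides Klrk1, Foxp3, Prf1, Klrc1, Klrc2, Ly6c2 and Il2ra, the lower ones included Snx9 (−0.96 ± 0.15), Hpgds (−0.89 ± 0.13), Slfn5 (−1.06 ± 0.16) and Nrp2 (−1.57 ± 0.41). The higher ones included the death receptor gene Tnfrsf25 (1.62 ± 0.26), the endoglin gene Eng (2.10 ± 0.39), Mical3 (1.57 ± 0.31), Fsd1l (1.03 ± 0.19), Dapl1 (2.72 ± 0.44), and the sort genes Tcf7 (1.24 ± 0.21) and Cd44 (0.67 ± 0.13). All these values are edgeR's log2 fold changes with SE, and in edgeR their adjusted p values were above the threshold except for Klrk1.

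Other genes followed in every comparison were Il7r (0.67 ± 0.33), Ccr7 (0.46 ± 0.29), Pdcd1 (0.83 ± 0.67), Lef1 (−0.07 ± 0.20), Tox (−0.34 ± 0.49) and Mki67 (0.18 ± 0.40), all with an adjusted p of 1. The signs of 3 of them rested on 1 library. Without low-from-low replicate 1, Lef1 became 0.32 and Mki67 −0.29. Without high-from-high replicate 2, Lef1 became 0.03, and without low-from-low replicate 2, Tox became 0.36. With length offsets Klrk1 (−1.37) was not called and Klrc1 was (−2.10). With the replicate number as a block Klrk1 (−1.30) was not called and Foxp3 was (−2.13). The call of Klrk1 was lost in the fit of the 4 libraries (−1.29) and in limma with a pseudocount of 1 (−1.31) or 0.1 (−1.34). It was also lost without high-from-high replicate 1 (−1.08), low-from-low replicate 1 (−1.28) or low-from-low replicate 2 (−1.34), and the count was 0 without either day 3 effector or either antigen-experienced library, which share the estimate of the spread. The count was 2 without either high-from-low library or low-from-low replicate 2, and 3 without either naive library. Foxp3 passed with DESeq2's size factors (−2.19), the strict filter (−2.18) or no low-count filter (−2.19). Foxp3 (−2.49) and Klrc2 (−2.68) passed without low-from-low replicate 2, and Tcf7 (1.70) without low-from-low replicate 1.

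**Figure D2:**
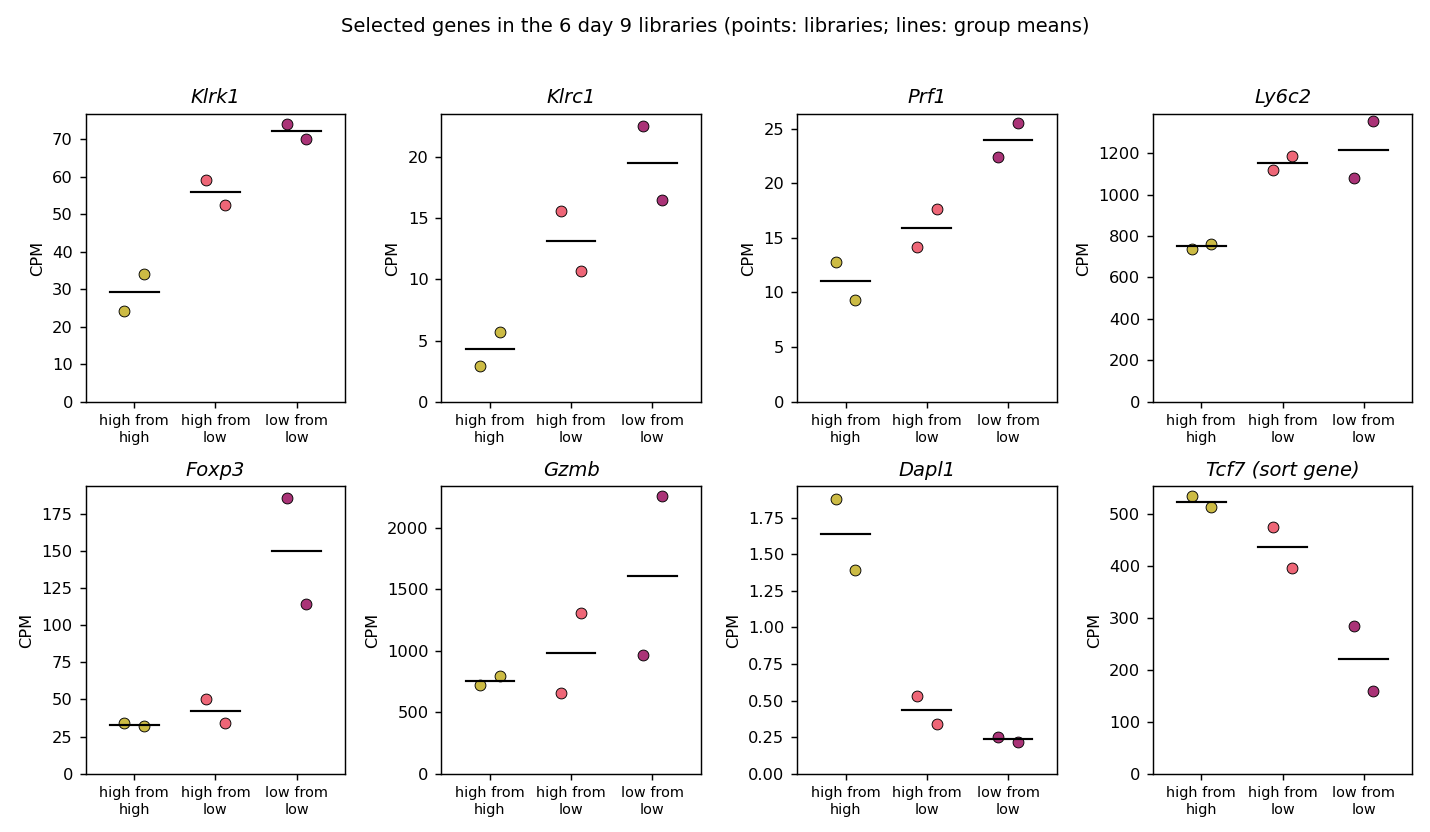
CPM of Klrk1, Klrc1, Prf1, Ly6c2, Foxp3, Gzmb, Dapl1 and Tcf7 in the 6 day 9 libraries, 1 point per library and a line at each group mean of 2 libraries. Klrk1 lay at 24.2 and 34.0 CPM in high-from-high, 52.5 and 59.0 CPM in high-from-low and 70.0 and 74.1 CPM in low-from-low cells.

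High-from-low and low-from-low cells shared the low day 3 sort and differed at the day 9 sort. They were compared for what goes with a high reporter on day 9 after a low day 3 sort. Whether single cells regained the reporter cannot be read from these libraries. Foxp3 was at 42.5 ± 11.5 CPM in the high-from-low cells against 150 ± 50.6 CPM (SD, n = 2 each), a log2 fold change of −1.82 ± 0.27 (adjusted p = 0.286). Effector and cytotoxic genes were lower in 31 of 38 cases, among them Prf1 (−0.59 ± 0.16) and Ifng (−0.50 ± 0.25), with 0 passing singly over all genes or adjusted over the list alone. Gzmb was at 653 and 1300 CPM against 966 and 2260 CPM (−0.72 ± 0.55), and without low-from-low replicate 2 its estimate was 0.02. edgeR called 0 of 15458 genes, with 146 at an unadjusted p under 0.05. That is below the 725 unchanged genes in the data simulated for high-from-high against low-from-low cells. The cause was not tested here either, and the lack of calls does not show that the groups are alike. DESeq2 called 3. Those, named after their values were seen, were Foxp3, the sort gene Tcf7 (0.97 ± 0.21, adjusted p = 1 in edgeR) and the predicted gene Gm6361. Gm6361 had no count in the high-from-low libraries and was at 4.25 and 5.44 CPM in the low-from-low ones, at least 31.1-fold lower. Without low-from-low replicate 1, edgeR called 1 gene, Tcf7, at 1.44.

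The effector and cytotoxic list fell (camera adjusted p = 2.25e-11, and adjusted p = 0.123 with an estimated correlation), as did the CD4 and regulatory T cell markers (8.66e-05, and adjusted p = 0.123 with an estimated correlation), where Foxp3 fell adjusted over the list alone. Foxp3 also fell adjusted over the T helper list alone. Naive and memory genes were higher in 23 of 34 cases (0.00368, and adjusted p = 0.581 with an estimated correlation), which turned downward without high-from-low replicate 1 (0.889) or low-from-low replicate 2 (0.374). Cell cycle genes were higher in 33 of 38 cases (2.64e-05, and adjusted p = 0.713 with an estimated correlation), and turned downward without low-from-low replicate 1 (1.4e-06) or high-from-low replicate 2 (0.0197). Smaller shifts downward were called for inhibitory receptor genes (0.0184, and adjusted p = 0.334 with an estimated correlation), virtual and central memory genes (0.035, and adjusted p = 0.432 with an estimated correlation), mitochondrial respiration (0.035, and adjusted p = 0.786 with an estimated correlation), interferon response (0.0446, and adjusted p = 0.775 with an estimated correlation) and chemokine receptors and adhesion (0.0494, and adjusted p = 0.568 with an estimated correlation). fry called none of these 9 lists, with adjusted p of 0.153 for effector and cytotoxic genes, 0.177 for CD4 and regulatory T cell markers, 0.715 for naive and memory genes, 0.812 for cell cycle genes and 0.497, 0.512, 0.829, 0.844 and 0.738 for the last 5. Each of the last 5 calls was also lost when 1 library was left out. Without high-from-low replicate 1 the adjusted p was 0.744 for inhibitory receptors, 0.446 for virtual memory, 0.928 for interferon and 0.661 for chemokine receptors. Without low-from-low replicate 2 it was 0.873, 0.707, 0.0772 (with the direction turned) and 0.493, and 0.78 for mitochondrial respiration. Chemokine receptors also missed the threshold without low-from-low replicate 1 (0.0511), and mitochondrial respiration without high-from-low replicate 2 (0.726). With length offsets it was 0.108 for inhibitory receptors, 0.156 for mitochondrial respiration, 0.278 for interferon and 0.264 for chemokine receptors. With no low-count filter it was 0.102 for virtual memory, 0.0772 for interferon and 0.128 for chemokine receptors, with the strict filter 0.074 and 0.0973 for the last 2, and with DESeq2's size factors 0.0545 for chemokine receptors. The remaining lists had camera adjusted p of 0.274 or more. The median, mean and test of the cholesterol, immediate early, T helper and NK lists did not all share a sign.

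Among the genes followed throughout, Il7r (0.53 ± 0.33), Cd44 (0.27 ± 0.13), Ccr7 (0.36 ± 0.29), Lef1 (0.15 ± 0.20), Tox (−0.40 ± 0.49), Pdcd1 (0.08 ± 0.73) and Mki67 (0.34 ± 0.40) had an adjusted p of 1. Without low-from-low replicate 1, Pdcd1 was −0.50 and Mki67 −0.12. Without high-from-low replicate 2, Pdcd1 was −0.48 and Mki67 −0.26. Lef1 became −0.02 and Tox 0.12 without high-from-low replicate 1, and −0.16 and 0.30 without low-from-low replicate 2.

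The fold changes of high-from-high and of high-from-low cells, both against the same low-from-low libraries, had a Pearson r of 0.516 across genes, which are not independent replicates. In 20 simulated draws of unchanged groups against shared controls r was 0.457 to 0.525. The covariance was 0.204, against 0.178 to 0.219 in the draws and 0.013 above their median. The number of genes called in the same direction in both comparisons was 0 in edgeR, as in every draw. It was 2 in DESeq2 and 21 with no low-count filter, for which unchanged groups were not simulated. The draws hold no difference that replicates of the same number share between groups. The low-from-low group has 2 libraries, too few to give 2 to each comparison, so part of any excess may come from the shared controls.

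High-from-low and high-from-high cells both had a high reporter on day 9 and differed at the day 3 sort, so they were compared for a trace of the earlier state. Tcf7 was at 475 and 397 CPM against 535 and 513 CPM. A trace of day 3 therefore cannot be told apart from a difference in Tcf7 level on day 9. Klrk1 was at 55.8 ± 4.61 CPM in the high-from-low cells against 29.1 ± 6.93 CPM (SD, n = 2 each), a log2 fold change of 0.93 ± 0.15. Klrc1 was at 13.1 ± 3.52 CPM against 4.33 ± 1.97 CPM (1.57 ± 0.34), Klrc2 at 7 ± 1.33 CPM against 2.63 ± 0.81 CPM (1.39 ± 0.35), and Ly6c2 at 1150 ± 47.7 CPM against 750 ± 18.5 CPM (0.62 ± 0.12). Dapl1 was lower, at 0.431 ± 0.134 CPM against 1.64 ± 0.345 CPM (−1.86 ± 0.41). edgeR called 0 genes over all 15458, and the adjusted p of Klrk1 was 0.729. An unadjusted p under 0.05 was found for 158 genes, also below the 725 unchanged genes in the data simulated for high-from-high against low-from-low cells. DESeq2 called 4 genes, which were Klrk1, Klrc1, Ly6c2 and the predicted gene Gm6361, named after their values were seen. Gm6361 had no count in the high-from-low libraries and was at least 15.4-fold lower there.

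In the effector and cytotoxic list, 25 of 38 genes were higher in high-from-low cells and 3 rose adjusted over the list alone (camera adjusted p = 9.03e-09, and adjusted p = 0.167 with an estimated correlation). That call held without each of the 4 libraries in turn and was lost with fry (adjusted p = 0.216). In the virtual and central memory list 2 of 23 rose adjusted over the list alone, and the list was called upward (0.00317, and adjusted p = 0.243 with an estimated correlation) although its median was −0.01 and its mean 0.13. It missed the threshold without high-from-high replicate 1 (0.111) or high-from-low replicate 2 (0.207). Cholesterol synthesis genes were higher in 17 of 22 cases (0.000199, and adjusted p = 0.513 with an estimated correlation), which was lost without high-from-high replicate 2 (0.207) or high-from-low replicate 2 (0.108). Immediate early and AP-1 genes were higher in 20 of 30 cases (0.00773, and adjusted p = 0.532 with an estimated correlation), which was lost with length offsets (0.25) or without high-from-low replicate 1 (0.249) and turned without high-from-high replicate 2 (0.362). fry did not call the virtual and central memory (adjusted p = 0.305), cholesterol synthesis (0.498) or immediate early list (0.639) either. The other lists had camera adjusted p of 0.061 or more, the naive and memory list 0.605, with 1 gene up and 1 down adjusted over the list alone. Median, mean and test did not all share a sign for the naive and memory, hypoxia, amino acid, B cell and heat shock lists.

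Of the genes followed throughout, Prf1 was at 0.54 ± 0.16 and Cd44 at −0.40 ± 0.13, with an adjusted p of 1 like the rest. These were Tcf7 (−0.27 ± 0.21), Il7r (−0.14 ± 0.32), Ccr7 (−0.10 ± 0.29), Lef1 (0.22 ± 0.20), Gzmb (0.37 ± 0.55), Ifng (0.36 ± 0.27), Pdcd1 (−0.75 ± 0.68), Tox (−0.06 ± 0.49) and Mki67 (0.16 ± 0.40). Without high-from-low replicate 2, Ccr7 was 0.07, Gzmb −0.21 and Mki67 −0.44, and without high-from-low replicate 1, Tox was 0.47. Without high-from-high replicate 2, Il7r was 0.08 and Tox 0.30, and without high-from-high replicate 1, Ccr7 was 0.07. Genes that differed between high-from-high and low-from-low cells and in which high-from-low cells also differed from high-from-high cells, toward low-from-low, numbered 0 in edgeR. In DESeq2 they numbered 3, Ly6c2, Klrk1 and Klrc1. Both comparisons use the high-from-high libraries, whose own spread moves a gene in this direction, and no value for unchanged groups was computed for this number.

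Antigen-experienced and naive cells were both reporter positive and differed in CD44, so their comparison gives the changes of memory-like spleen cells. Cxcr3, a chemokine receptor gene of memory and effector cells (chromosome X, 101731535 to 101734269), was at 215 ± 6.63 CPM against 2.23 ± 1.07 CPM, and Il2rb, the receptor chain for interleukins 2 and 15, at 1160 ± 41.9 CPM against 166 ± 2.66 CPM (SD, n = 2 each). Tbx21, which encodes the transcription factor T-bet, rose by a log2 fold change of 5.99 ± 0.27 (edgeR adjusted p = 3.13e-07). Among genes that fell were Ccr9, a receptor for gut homing (chromosome 9, 123678439 to 123784330; −4.69 ± 0.27, adjusted p = 1.08e-06), and Itgae, the CD103 integrin gene (−3.62 ± 0.27). Of 15458 genes, 1042 passed, 678 higher and 364 lower, and 654 of these differed by 2-fold or more. For every gene named here as changed, both libraries of a group lay on the same side of both libraries of the other.

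All 23 virtual and central memory genes had a positive estimate. Of these, 20 rose over all genes and 23 rose adjusted over the list alone (camera adjusted p = 6.07e-107, and adjusted p = 0.000265 with an estimated correlation). Besides Cxcr3 and Il2rb they included Ly6c2 (3.15 ± 0.13), the interleukin 18 receptor gene Il18r1 (1.87 ± 0.12) and Itgb1 (2.39 ± 0.17), the integrin beta 1 gene. Of 38 effector and cytotoxic genes, 21 rose and 1 fell, and 25 rose adjusted over the list alone (1.77e-41, and adjusted p = 0.0212 with an estimated correlation). Beside Tbx21 these held Il18rap (4.61 ± 0.18), which encodes the other chain of the interleukin 18 receptor. Prf1 rose by 0.90 ± 0.15 (adjusted p = 0.00257), and Klre1, a killer cell receptor gene, by 5.12 ± 0.36. Ifng had no count in the naive libraries and was at 1.05 and 1.08 CPM in the antigen-experienced ones, at least 8.68-fold higher. Of 9 NK and gamma-delta T cell markers, 5 rose and 6 rose adjusted over the list alone (3.01e-10, and adjusted p = 0.0894 with an estimated correlation), among them Tcrg-C1, a gamma chain constant region gene (5.61 ± 0.65). Genes of the Klra family, which encode Ly49 receptors, were among the widest differences, with no count in either naive library. Klra7 was at least 334-fold, Klra6 at least 253-fold, Klra10 at least 184-fold and Klra3 at least 166-fold higher, subject to reads shared within the family. Cd163l1, a scavenger receptor gene (chromosome 7, 140218267 to 140231145), was at least 974-fold higher. Samd3 (8.59 ± 0.34), Runx2 (5.43 ± 0.24), which encodes a transcription factor, and S100a6 (7.25 ± 0.43) also rose.

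Inhibitory receptor genes rose in 10 of 21 cases, with 11 up and 2 down adjusted over the list alone (3.83e-07, and adjusted p = 0.0894 with an estimated correlation), among them Lag3 (3.42 ± 0.47), Tigit (4.29 ± 0.62) and Cd38 (3.62 ± 0.51). Pdcd1, the PD-1 gene, was at 1.68 ± 0.91 (adjusted p = 0.392) and passed at 7.51 without naive replicate 2, while Tox was at −0.08 ± 0.45. Cell cycle genes rose in 10 of 38 cases and in 22 adjusted over the list alone (1.45e-13, and adjusted p = 0.532 with an estimated correlation), a list that fry did not call (adjusted p = 0.0624). Mki67, a proliferation marker, was at 52.2 and 32.3 CPM against 3.63 and 2.72 CPM (3.74 ± 0.50, adjusted p = 0.00202), a call lost in limma with a pseudocount of 1 (1.70) or 0.1 (2.58). Cytokine and receptor genes rose in 10 and fell in 3 of 34 cases, or 14 and 5 adjusted over the list alone (1.79e-08, and adjusted p = 0.0894 with an estimated correlation), and chemokine receptor and adhesion genes in 9 and 4 of 30, or 11 and 7 adjusted over the list alone (0.00604, and adjusted p = 0.432 with an estimated correlation), the latter lost with length offsets (0.104). Cxcr5, a receptor for B cell follicle homing, rose by 4.14 ± 0.36 (adjusted p = 5.75e-05), a call lost in limma with a pseudocount of 0.1 (4.08). Cholesterol synthesis genes fell in 13 of 22 cases and in 16 adjusted over the list alone (2.23e-16, and adjusted p = 0.123 with an estimated correlation). These included Sqle (−2.16 ± 0.19) and Cyp51 (−1.12 ± 0.15), enzymes of the pathway.

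Of 34 naive and memory genes, 8 rose and 4 fell, or 10 and 5 adjusted over the list alone. Myb (2.58 ± 0.18) and the co-receptor gene Cd28 (1.02 ± 0.12) rose. Lef1, a partner factor of TCF1, fell by 1.04 ± 0.20 (SE; adjusted p = 0.0115), a call lost without antigen-experienced replicate 1 (−1.01) or 2 (−1.03) or naive replicate 1 (−1.03), and in limma with either pseudocount (−0.84). Igfbp4 (−3.58 ± 0.52), Tgfbr3 (−2.76 ± 0.16), Gpr83 (−4.97 ± 0.60) and Plaur (−4.95 ± 0.62) fell too. The list's camera test was upward (0.0251, and adjusted p = 0.711 with an estimated correlation), as was its mean of 0.41, whereas its median was −0.16, and the call was lost with no low-count filter (0.639), with fry (0.144) or without naive replicate 2 (0.154). Il7r (0.44 ± 0.32, adjusted p = 0.546), Ccr7 (−0.70 ± 0.29, adjusted p = 0.235) and Tcf7 (−0.03 ± 0.21) did not pass, and Tcf7 was 0.01 without naive replicate 2. Cd44, the sort gene, was 6.90 ± 0.17 higher. Gzmb was at 0.545 and 0.677 CPM against 1.77 and 0 CPM in naive replicates 1 and 2, and its estimate of −0.46 ± 1.31 became 6.76 without naive replicate 1.

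Of 8 B cell markers, 2 rose, Cd22 (5.43 ± 0.38) and Ighd (2.12 ± 0.48), beside these groups (0.0196, and adjusted p = 0.372 with an estimated correlation). That list call was lost with length offsets (0.262) or without antigen-experienced replicate 1 (0.0642) or 2 (0.0886) or naive replicate 2 (0.146). The call of Ighd was lost without the same libraries (2.15, 2.14 and 1.74) and in limma with a pseudocount of 0.1 (2.16). The glycolysis list (3 up of 20), T helper list (7 up and 4 down of 27), Wnt list (3 up and 4 down of 17), immediate early list (4 up and 1 down of 30) and interferon list (1 up and 2 down of 30) did not pass, nor did hypoxia, mitochondrial, fatty acid, amino acid, chromatin, heat shock, myeloid, stromal and CD4 lists, with camera adjusted p from 0.105 to 0.976. Adjusted over the list alone, glycolysis had 8 up and 2 down, T helper 8 and 6, Wnt 4 and 5, and immediate early 5 and 3. Median, mean and test differed in sign for the hypoxia, mitochondrial, fatty acid, interferon, Wnt and CD4 lists. The count of 1042 was 519 without antigen-experienced replicate 1, 470 without replicate 2, 606 without naive replicate 1 and 1706 without naive replicate 2, and 1840 with no low-count filter. Naive replicate 1 is the library with 15050 detected genes.

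The only gene called between high-from-high and low-from-low cells, Klrk1, went the opposite way here, higher in antigen-experienced than in naive cells (1.65 ± 0.15, adjusted p = 4.24e-05). With 1 call there, independent lists would share 0.02 downward calls, and Fisher's exact test of the overlap, which counts calls in either direction, cannot give a two-sided p under 0.0674, so it decides nothing. Across genes, the fold changes of both comparisons had a Pearson r of −0.069.

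Day 3 effector cells were compared with naive cells, and differences reached most of the genes tested. The groups differ in activation, in ex vivo culture and in the spleen sort, and these cannot be told apart here. Ifng (chromosome 10, 118441046 to 118445892) was at 5550 and 3690 CPM with no count in the naive libraries, at least 37800-fold higher, and Gzmb (chromosome 14, 56258838 to 56262260) was at 9750 and 8740 CPM against 1.77 and 0 CPM. Il2ra was at 3030 and 3250 CPM against 1.82 and 2.1 CPM, a log2 fold change of 10.64 ± 0.16 (edgeR adjusted p = 5.44e-12). Klf2, a transcription factor gene of quiescence and lymphoid homing (chromosome 8, 72319033 to 72321656), was at 1.66 and 1.29 CPM against 572 and 538 CPM (−8.57 ± 0.28, adjusted p = 1.68e-09). Of 15458 genes, 9791 passed, 5081 higher and 4710 lower, and 6581 differed by 2-fold or more. For every gene named here as changed, both libraries of a group lay on the same side of both libraries of the other.

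Of 38 effector and cytotoxic genes, 31 rose and 2 fell, or 3 adjusted over the list alone (camera adjusted p = 1.11e-20, and adjusted p = 0.0703 with an estimated correlation). Prf1 rose by 3.22 ± 0.16 and Tbx21 by 7.01 ± 0.28. Of 34 cytokine and receptor genes, 23 rose and 7 fell (4.15e-07, and adjusted p = 0.0966 with an estimated correlation), with Il12rb2, an interleukin 12 receptor chain, at 10.65 ± 0.39, Il2rb at 2.72 ± 0.14 and Ltb, the lymphotoxin beta gene, at −2.72 ± 0.12. The chemokine genes Ccl3 and Ccl4, which are related in sequence, were at least 10300-fold and 4480-fold higher. Lgals3, a galectin gene, was at least 4960-fold, the metallothionein genes Mt1 and Mt2 at least 4100-fold and 3310-fold, the CD30 gene Tnfrsf8 at least 2070-fold and the transcription factor gene Batf3 at least 1450-fold higher. Of 21 inhibitory receptor genes, 15 rose and 4 fell (6.7e-06, and adjusted p = 0.127 with an estimated correlation), among them Lag3 (9.45 ± 0.43) and Pdcd1 (8.44 ± 0.75), while Tox fell (−3.84 ± 0.54, adjusted p = 0.00017). Immediate early and AP-1 genes rose in 18 and fell in 3 of 30 cases (2.64e-05, and adjusted p = 0.302 with an estimated correlation), with Nr4a2 at 10.09 ± 0.44 and Fosl2 at 3.57 ± 0.15. Irf4, a transcription factor gene induced by T cell receptor signals, rose by 7.48 ± 0.30.

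All 38 cell cycle genes rose (4.27e-15, and adjusted p = 0.53 with an estimated correlation), among them Mki67 (7.88 ± 0.57) and E2f1 (5.20 ± 0.40). Glycolysis genes rose in 19 and fell in 1 of 20 cases (1.31e-22, and adjusted p = 0.0966 with an estimated correlation), with Tpi1 at 5.53 ± 0.14, Pgk1 at 4.33 ± 0.16 and Ldha, the lactate dehydrogenase gene (chromosome 7, 46841475 to 46855627), at 3490 and 3780 CPM against 272 and 275 CPM. Amino acid and stress response genes rose in 20 of 21 cases (3.73e-13, and adjusted p = 0.0894 with an estimated correlation), including Psat1 (4.36 ± 0.16), an enzyme gene of serine synthesis, Slc7a5 (3.25 ± 0.12), an amino acid transporter gene, and the asparagine synthetase gene Asns, at least 1060-fold higher. Cholesterol synthesis genes rose in 21 of 22 cases (3.48e-09, and adjusted p = 0.243 with an estimated correlation), with Cyp51 at 3.20 ± 0.15. Mitochondrial respiration genes rose in 36 of 40 cases (3.53e-08, and adjusted p = 0.532 with an estimated correlation), with Uqcrfs1 at 2.19 ± 0.09, and hypoxia response genes in 14 of 17 (1.95e-06, and adjusted p = 0.513 with an estimated correlation), with Egln3 at 6.85 ± 0.27. Mitochondrially encoded RNA was 4.22% and 3.63% of counts, against 2.48% and 2.54% in naive cells. Heat shock genes rose in 11 and fell in 2 of 14 cases (0.00091, and adjusted p = 0.369 with an estimated correlation), with Hsp90aa1 at 3.47 ± 0.16.

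Naive and memory T cell genes fell in 29 and rose in 4 of 34 cases (2.34e-10, and adjusted p = 0.243 with an estimated correlation). Lef1 (−2.63 ± 0.22), Il7r (−1.59 ± 0.33, adjusted p = 0.00222), Dapl1 (−6.49 ± 0.29) and Rasgrp2 (−6.71 ± 0.24), an activator of the small GTPase Rap1, were lower, as was the sort gene Tcf7 (−5.37 ± 0.25), while Cd44 was higher (6.68 ± 0.17). Ccr7, a receptor for lymph node entry, was at 240 and 423 CPM against 402 and 417 CPM (−0.31 ± 0.29, adjusted p = 0.377) and at 0.05 without day 3 effector replicate 1. Interferon response genes fell in 24 and rose in 4 of 30 cases (4.42e-10, and adjusted p = 0.404 with an estimated correlation), with Irf7 at −5.60 ± 0.23 and Xaf1 at −6.66 ± 0.21. Ifit1bl1 was at least 618-fold, Ifit3 at least 170-fold and Rtp4 at least 147-fold lower. Wnt and TCF1-associated genes fell in 9 and rose in 3 of 17 cases (0.00599, and adjusted p = 0.243 with an estimated correlation), with Axin2, a target of Wnt signals, at −4.31 ± 0.17. Chemokine receptor and adhesion genes fell in 16, or 17 adjusted over the list alone, and rose in 6 of 30 (0.00773, and adjusted p = 0.372 with an estimated correlation), with Ccr9 at −7.40 ± 0.33 and Itgae at −6.60 ± 0.33.

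Virtual and central memory genes (13 up and 8 down of 23, or 9 down adjusted over the list alone), T helper genes (13 up and 9 down of 27, or 10 down adjusted over the list alone), chromatin genes (18 up and 15 down of 38) and fatty acid oxidation genes (11 up and 3 down of 19) changed in both directions, with camera adjusted p from 0.361 to 0.682. On balance, fry called virtual and central memory (adjusted p = 0.0047), T helper (0.00675) and fatty acid oxidation genes (0.000134) upward, but not chromatin genes (0.168). Among markers of other cells, H2-Ab1, an MHC class II gene, was at 25.1 and 75.7 CPM against 0 and 0.229 CPM, and Cd74, the class II invariant chain, at 32.7 and 45.3 CPM against 1.25 and 2.33 CPM. Ighm, the immunoglobulin mu gene, was at 25.9 and 15.8 CPM against 440 and 445 CPM. The B cell (1 up and 5 down of 8), myeloid (2 up and 1 down of 9), NK (3 up and 1 down of 9), CD4 (4 up and 1 down of 7) and stromal (1 up and 1 down of 6) lists had camera adjusted p from 0.121 to 0.801. Of these, fry called the B cell list downward (adjusted p = 0.000629) and the CD4 list upward (0.000558). It did not call the myeloid (0.117), NK (0.295) or stromal list (0.0839). Neutrophil and erythroid markers had too few tested members, and their highest values in any library were 6.17 CPM for Ly6g and 5.06 CPM for Itga2b. Median, mean and test differed in sign for the chromatin, myeloid and stromal lists. The median log2 fold change of all genes, against which these changes are read, was −0.04, and −0.14 on log2 (TPM + 0.1). The count was 8761 to 10048 when 1 of the 4 libraries was left out, and 9072 without naive replicate 1, the library with fewer detected genes.

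High-from-high day 9 cells were set against antigen-experienced spleen cells, to measure how cultured cells with a high reporter differed from memory-like cells taken from the animal. These groups also differ in ex vivo culture and in the spleen sort with its handling, and such sources cannot be told apart here. Il2ra was at 609 and 610 CPM against 2.35 and 2.79 CPM, a log2 fold change of 7.89 ± 0.14 (edgeR adjusted p = 5.3e-11), and Gzmb at 757 ± 54.2 CPM against 0.611 ± 0.0937 CPM (10.26 ± 0.92, adjusted p = 7.3e-05; SD, n = 2 each). Prf1 fell by 3.58 ± 0.17 (SE, log2) and Klrk1 by a log2 fold change of −2.56 ± 0.16. Cxcr5 (chromosome 9, 44511787 to 44561877) was at 0.176 and 0.188 CPM against 111 and 111 CPM (−9.20 ± 0.54). Of 15458 genes, 4439 passed, 2526 higher and 1913 lower, and 2082 differed by 2-fold or more. For every gene named here as changed, both libraries of a group lay on the same side of both libraries of the other.

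Naive and memory genes fell in 23 and rose in 3 of 34 cases, or 25 fell adjusted over the list alone (camera adjusted p = 1.6e-08, and adjusted p = 0.302 with an estimated correlation). Dapl1 (−5.13 ± 0.28), Il6st (−3.53 ± 0.25), the shared receptor chain for interleukin 6, Id3 (−3.12 ± 0.28) and Il7r (−2.19 ± 0.34, adjusted p = 0.0013) were lower. Tcf7, a sort gene, was at −1.16 ± 0.21 and Cd44 at −2.36 ± 0.13. Ccr7, at −0.90 ± 0.29 (adjusted p = 0.0447), missed the threshold without high-from-high replicate 1 (−1.07) or 2 (−0.75) or antigen-experienced replicate 1 (−0.92) or 2 (−0.83), and in limma with a pseudocount of 1 (−0.80) or 0.1 (−0.81). Lef1 was at −0.50 ± 0.20 (adjusted p = 0.095). Virtual and central memory genes fell in 10 and rose in 6 of 23 cases, or 11 fell adjusted over the list alone (0.00738, and adjusted p = 0.293 with an estimated correlation), with Samd3 at −3.20 ± 0.24. Klra7, with no count in the day 9 libraries, was at least 282-fold lower, and Cd163l1 was at −7.71 ± 0.38. Effector and cytotoxic genes went both ways, 15 up and 10 down of 38, or 17 and 11 adjusted over the list alone (0.0175, and adjusted p = 0.568 with an estimated correlation). That call was lost with no low-count filter (0.309) or without antigen-experienced replicate 1 (0.056). Ifng rose by 1.44 ± 0.32 (adjusted p = 0.0073), a call lost without high-from-high replicate 2 (1.41). Of 21 inhibitory receptor genes, 6 rose and 8 fell, or 7 and 8 adjusted over the list alone (0.736). Tox was at −2.40 ± 0.49, lost without high-from-high replicate 1 (−2.13), and Pdcd1 at 1.18 ± 0.68 (adjusted p = 0.243).

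Cell cycle genes rose in 34 of 38 cases and in 36 adjusted over the list alone (5.95e-22, and adjusted p = 0.372 with an estimated correlation), among them Nusap1 (4.56 ± 0.44), Ube2c (4.98 ± 0.50), Ccnb1 (4.62 ± 0.47) and Mki67 (3.93 ± 0.45). Cholesterol synthesis genes rose in 17 of 22 cases (1.98e-11, and adjusted p = 0.211 with an estimated correlation), with Acat2 at 2.55 ± 0.14, Cyp51 at 2.60 ± 0.15 and Sqle (chromosome 15, 59315077 to 59331192) at 2.64 ± 0.19. Interferon response genes rose in 13 and fell in 3 of 30 cases (0.00317, and adjusted p = 0.711 with an estimated correlation). Gbp2, a guanylate-binding protein gene (chromosome 3, 142620602 to 142638008), was at 555 and 497 CPM against 57.8 and 55.4 CPM, and Gbp3 (2.77 ± 0.13) rose with it. Ifitm1, an interferon-induced membrane protein gene (chromosome 7, 140967221 to 140969825), was at 265 and 233 CPM with no count in the antigen-experienced libraries, at least 2030-fold higher, and Ifitm2 was at least 381-fold higher. Mitochondrial respiration genes rose in 20 and fell in 2 of 40 cases, or 23 and 2 adjusted over the list alone (0.0026, and adjusted p = 0.731 with an estimated correlation), with Uqcrfs1 at 0.53 ± 0.09. Glycolysis genes rose in 12 of 20 cases, or 13 up and 2 down adjusted over the list alone (0.0125, and adjusted p = 0.642 with an estimated correlation), with Pgk1 at 0.96 ± 0.14, a list call lost with the strict filter (0.0655). Hypoxia genes rose in 6 of 17 cases (0.0101, and adjusted p = 0.711 with an estimated correlation) and amino acid and stress genes in 8 of 21, with 1 lower (0.0131, and adjusted p = 0.513 with an estimated correlation).

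Immediate early and AP-1 genes fell in 17 and rose in 4 of 30 cases (0.00119, and adjusted p = 0.432 with an estimated correlation). Nr4a1 (−4.70 ± 0.50) and Egr3 (−4.50 ± 0.49), genes induced by T cell receptor signals, and Nfkbia (−1.14 ± 0.13) fell, and Jun rose (3.37 ± 0.17). The heat shock list did not pass (0.224; 2 up and 4 down of 14), its median of 0.05 and mean of −0.85 differing in sign, while Hspa1a (−5.79 ± 0.52) and Hspa1b (−7.04 ± 0.35), which are near-identical copies, fell. Foxp3 rose by 5.26 ± 0.36 and Ctla4 by 2.54 ± 0.49, the latter lost with DESeq2 (2.55), in limma with a pseudocount of 0.1 (2.65) and without antigen-experienced replicate 2 (2.44), in a CD4 and regulatory T cell list that did not pass (0.39) and whose median and mean also differ in sign. Itgae rose by 4.24 ± 0.27 and Cish, an inhibitor of cytokine signalling, by 6 ± 0.46. Lgals3 rose by 10.37 ± 0.40, and Ccn3, Cdkn2a, the gene of p16INK4a, and Thbs1 were at least 219-fold, 147-fold and 72.7-fold higher. Of 8 B cell markers, 4 fell, among them Cd22 (−5.51 ± 0.39) and Ighd (−5.45 ± 0.60), beside these groups (0.00532, and adjusted p = 0.293 with an estimated correlation). The chemokine, cytokine, chromatin, T helper, Wnt, fatty acid, myeloid, NK and stromal lists did not pass, with camera adjusted p from 0.0805 to 0.793, and the T helper list had a median of −0.02 and a mean of 0.49. Of these, fry called fatty acid (adjusted p = 0.000926) and cytokine genes (0.00787) upward. It called Wnt (0.0086), chromatin (0.026) and NK genes (0.0452) downward, and the rest had fry adjusted p from 0.144 to 0.709. The count of 4439 was 2766 without high-from-high replicate 1, 2715 without replicate 2, 2593 without antigen-experienced replicate 1, 2448 without replicate 2 and 7167 in a fit of the 4 libraries alone.

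**Figure D3:**
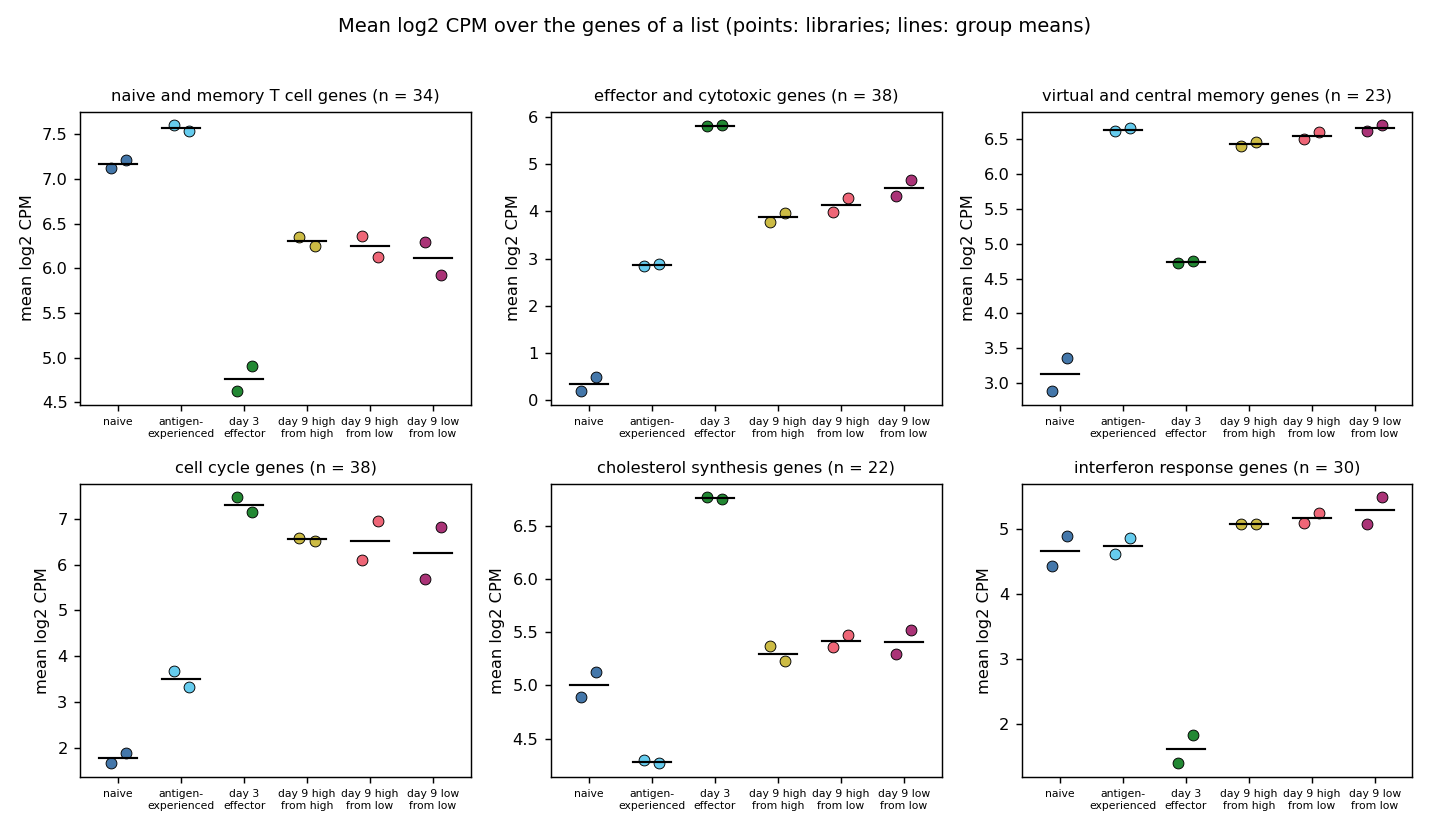
Mean log2 CPM of 6 gene lists in the 12 libraries, 1 point per library, by group. Cell cycle genes averaged 7.14 and 7.47 in day 3 effector, 5.68 to 6.95 in day 9, 3.32 and 3.68 in antigen-experienced and 1.66 and 1.88 in naive libraries.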

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

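The fits with a block for the low-origin groups, with the 6 day 9, 8 cultured or 11 libraries, and the counts without a library outside the comparison were chosen after the data were seen. Over all settings, 504 list tests and 2522 values of named genes, each under 1 setting, kept their direction and their side of the threshold, 121 and 32 lost the call, 3 and 82 gained one, and 10 and 29 changed direction. Of the counts, 100 stayed within 1.5 times the reported one and 57 did not. Where a result changed, the cause was not tested, except that fits of fewer libraries estimate the spread from fewer samples and fits without the low-count filter test more genes. Counts of high-from-high against low-from-low cells were simulated at the actual depth, with 2 libraries per group. In them 200 genes were changed, which makes the adjustment less strict than few changed genes do. Of 100 genes at 5 CPM or more with a 2-fold change, 73 were called. The part of depth in the missed ones was not separated from that of the spread or the number of libraries, and genes below 5 CPM were not among those changed.

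For high-from-high against low-from-low cells, 1 gene was called. The count was 2 with DESeq2's size factors or the strict filter, 25 with the DESeq2 Wald test, 105 with no low-count filter, and 0 in a fit of the 4 libraries, in limma with either pseudocount, and in fits of the 6 day 9 or 8 cultured libraries. For high-from-low against low-from-low cells the count of 0 became 3 with the DESeq2 Wald test, 30 with no filter and 2 in limma with a pseudocount of 0.1. For high-from-low against high-from-high cells it became 4, 38 and 1 under these settings and 2 in the fit of 4 libraries. Without each of the 12 libraries in turn the 3 counts ran from 0 to 3, from 0 to 1 and from 0 to 1: the first was 0 without high-from-high replicate 1, 2 without low-from-low replicate 2 and 3 without either naive library, the second 1 without low-from-low replicate 1 and the third 1 without either naive library. The count for antigen-experienced against naive cells was 1840 with no filter and 470 to 1706 without each library compared, the highest without naive replicate 2 and 606 without naive replicate 1. That for high-from-high against antigen-experienced cells was 7167 in the fit of 4 libraries and 2448 to 2766 without each library compared. It was 4691 without naive replicate 1 and 4942 and 4957 without day 3 effector replicates 1 and 2, which share the estimate of the spread. The number of genes called in the same direction in both comparisons against low-from-low cells was 2 with DESeq2, 21 with no filter (1 more was called in opposite directions) and 0 to 1 without each library compared. The number changed the same way between high-from-high and low-from-low as between antigen-experienced and naive cells was 1 with DESeq2's size factors or the strict filter, 3 with the DESeq2 Wald test, 23 with no filter and 0 to 1 without each library compared. Called in opposite directions were 1, 13, 52 and 0 to 2 in these settings. Genes of high-from-low cells that differed toward low-from-low numbered 3 with DESeq2, 26 with no filter and 1 without either naive library. The 26 included pseudogenes, predicted genes and T cell receptor segments, and the 1 was the receptor segment Trav7d-2. Camera with an estimated correlation called 2 of the list tests, against 57.

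The labels share replicate numbers, but nothing says that a number marks an animal or batch. Differences between replicates 1 and 2 correlated across genes at 0.283 between high-from-low and low-from-low cells and at −0.046 to 0.107 between the other pairs of groups. With the replicate number as a block, the 3 day 9 comparisons had 1, 1 and 0 calls. The 1 gene called between high-from-high and low-from-low cells was then Foxp3 (−2.13), and Klrk1 (−1.30) was not called. The number of genes called in both comparisons against low-from-low cells was 1, and the number changed the same way as between antigen-experienced and naive cells was 1, with 0 in the opposite direction. Cell cycle genes between high-from-low and low-from-low cells stayed called upward (camera adjusted p = 0.00028), with a mean log2 CPM of 6.10 against 5.68 in the replicates numbered 1 and 6.95 against 6.81 in those numbered 2. The block also ended the call of Ccr7 between high-from-high and antigen-experienced cells (−0.91) and 5 list calls. Camera's adjusted p became 0.669 for naive and memory genes between antigen-experienced and naive cells and 0.0799 for virtual and central memory genes between high-from-low and high-from-high cells. Between high-from-high and antigen-experienced cells it became 0.197 for effector and cytotoxic genes, 0.197 for virtual and central memory genes and 0.0786 for amino acid and stress response genes. A block for the low-origin groups alone gave 18, 2 and 0 calls in the 3 day 9 comparisons. With the 6 day 9 libraries it gave 289, 54 and 23, with the 8 cultured ones 16, 1 and 0, and with 11 libraries (naive replicate 1 left out) 23, 1 and 2. In the fit of the 6 day 9 libraries with this block, 41 genes were higher and 6 lower in both comparisons against low-from-low cells, and 19 genes of high-from-low cells differed toward low-from-low. In the same fit without the block these numbers were 0. Among the 19 were predicted genes and T cell receptor segments. The comparisons behind each number share 2 libraries, and unchanged groups were not simulated for this fit, so the numbers are no measure of agreement. With the block in the fits of 12, 8 and 11 libraries, 2, 1 and 1 genes were called in both comparisons, and 0, 0 and 2 differed toward low-from-low. The last 2 were Ccl5 and the receptor segment Trav7d-2.

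The named genes whose direction changed were not past the threshold with all libraries. In limma with a pseudocount of 1 and of 0.1, the log2 fold change of Lef1 in high-from-high against low-from-low cells was 0.02 and 0.02, and in high-from-low against high-from-high cells that of Tox was 0.08 and 0.11. Tox was 0.17 there with length offsets, and Gzmb between antigen-experienced and naive cells was 0.67 with the pseudocount of 0.1. Without each library in turn, high-from-high against low-from-low estimates ran from −0.38 to 0.32 for Lef1, −0.86 to 0.36 for Tox and −0.29 to 0.84 for Mki67. High-from-low against low-from-low they ran from −0.16 to 0.55 for Lef1, −1.30 to 0.02 for Gzmb, −1.19 to 0.30 for Tox, −0.50 to 0.76 for Pdcd1 and −0.26 to 1.00 for Mki67. High-from-low against high-from-high they ran from −0.32 to 0.08 for Il7r, −0.29 to 0.07 for Ccr7, −0.21 to 0.78 for Gzmb, −0.85 to 0.47 for Tox and −0.44 to 0.58 for Mki67. Between antigen-experienced and naive cells they ran from −0.02 to 0.01 for Tcf7 and −1.47 to 6.76 for Gzmb, and between day 3 effector and naive cells from −0.76 to 0.05 for Ccr7.

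Lists also turned without 1 library, most of them past the threshold with all libraries. For cell cycle genes the turned direction was itself past it: camera's adjusted p in high-from-high against low-from-low cells was 3.74e-06 without low-from-low replicate 1 (range without each library compared 2.55e-33 to 0.0386). In high-from-low against low-from-low cells it was 1.4e-06 without low-from-low replicate 1 and 0.0197 without high-from-low replicate 2 (1.52e-40 to 0.0197). The other turned lists were not past it. Without low-from-low replicate 2, high-from-high against low-from-low cells turned for naive and memory genes (0.157, range 4.44e-09 to 0.482) and interferon response genes (0.78, range 8.78e-12 to 0.78). High-from-low against low-from-low cells turned for the same lists, at 0.374 (1.22e-12 to 0.889) and 0.0772 (5.35e-08 to 0.928), and naive and memory genes also without high-from-low replicate 1 (0.889). Without high-from-high replicate 2, immediate early genes turned against low-from-low cells (0.288, range 1.55e-08 to 0.379) and between high-from-low and high-from-high cells (0.362, range 3.19e-10 to 0.362).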

Other observations

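The tests of values set to 0 and of fewer distinct molecules in naive replicate 1, of a batch and of shared cells behind the low-origin replicate differences, and of other T cells behind Foxp3 were chosen after the result was seen. The genes of the next paragraph were also chosen after their values were seen.

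Klrk1, the gene called between the day 9 groups, was at 182 and 163 CPM in antigen-experienced, 152 and 144 CPM in day 3 effector and 50.2 and 59.4 CPM in naive libraries, all but the naive ones above every day 9 library. Foxp3 was at 0.43 and 0.25 CPM in day 3 effector, 0.8 and 0.92 CPM in antigen-experienced and 3.98 and 6.31 CPM in naive libraries, below all 6 day 9 libraries. Tcrg-C2, a constant region gene of the T cell receptor gamma chain, was at 100 and 113 CPM in high-from-high cells against 11.1 and 9.88 CPM in antigen-experienced cells (log2 fold change 3.35 ± 0.57, edgeR adjusted p = 0.00217). In high-from-low cells it differed between the libraries, at 55.2 and 131 CPM, and in low-from-low cells at 39.4 and 112 CPM, while Trdc, the delta chain gene, was at most 10.6 CPM. Il23r, the interleukin 23 receptor gene, was at 15.7 and 28.8 CPM in day 3 effector libraries and at most 0.12 CPM in the other 10. Ighm was at 440 and 445 CPM in naive, 489 and 487 CPM in antigen-experienced, 25.9 and 15.8 CPM in day 3 effector and 206 to 355 CPM in day 9 libraries, whereas the B cell gene Cd79a was at most 3.7 CPM in any library.

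Naive replicate 1 listed 15050 genes with at least 1 count, against 17488 or more in each of the other 11 libraries. Lower depth is argued against, since naive replicate 2 thinned to the same total listed at least 17997 genes in each of 10 draws. Among 2209 genes at 10 to 30 counts in naive replicate 2, 27.16% were at 0 in replicate 1. Removal of only lower values per gene before deposit would not give this share. A higher cutoff would also have removed genes at 1 to 4 counts, of which replicate 1 kept 948. A cutoff per transcript was not tested. In the other 5 replicate pairs the highest such share was 2.60%. That gap is what a library built from fewer distinct molecules could show, but the reverse share, genes at 0 in naive replicate 2, was 6.59%: the test as first run included it and then missed its 5-fold bound, and comparing with only the other 5 pairs was settled after the values were seen. A biological difference between the naive samples was not tested and stays open.

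Differences between replicates 1 and 2 correlated across genes at 0.283 between high-from-low and low-from-low cells. In these 2 groups the median difference of cell cycle genes was −0.90 and −1.15 (log2), against 0.09 in high-from-high cells. A batch tied to the number in all cultured libraries is argued against by a median correlation of 0.018 over the other 5 pairs of cultured groups, and GC content and transcript length by a correlation of 0.281 once their trends were taken out, with values for 99.9% of the genes. That cultures of the same number shared their day 3 sorted cells cannot be told apart from a later shared handling, because the labels tie the numbers to no culture. Other biological sources of the shared difference stay open as untested.

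Foxp3 was at 186 and 114 CPM in low-from-low cells and at 50.6 CPM or less in the other day 9 libraries. Regulatory or other CD4 T cells in the sorted cells, which the labels call CD8 T cells, are argued against by Cd4, at most 0.27 CPM in the low-from-low libraries, while Ctla4, which activated CD8 T cells also express, was at 74 and 49.2 CPM there against 44.2 and 41 CPM in high-from-high cells. Reads of Ccdc22, which overlaps the 3' end of Foxp3 on the opposite strand (chromosome X, 7593809 to 7605517), are argued against by its log2 difference of −0.32 ± 0.15 between high-from-high and low-from-low cells, against −2.18 ± 0.27 for Foxp3. As a hypothesis, CD8 T cells with a low reporter at both sorts may express more Foxp3. The difference was called by the DESeq2 Wald test (−2.19) and by edgeR with DESeq2's size factors, the strict filter or no low-count filter. It was also called with the replicate number as a block (−2.13). It was not called by edgeR as reported (adjusted p = 0.0642), with length offsets or in limma. Fits of the 4, 6 day 9 or 8 cultured libraries did not call it either. Of the 4 libraries compared, only leaving out low-from-low replicate 2 gave a call. Whether a few cells express much or many express little cannot be read from these libraries.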
